A study of Mus musculus with 8 samples.

How the data were processed

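The samples were Ly6C-high classical monocytes from mouse bone marrow of 4 genotypes, with 2 libraries each and 8 in all. Per the labels, libraries were made from 10 ng of total RNA with a full-length cDNA kit (SMARTer Ultra Low), amplified for 12 to 15 cycles and sequenced as paired 150-base reads. The labels give genotype and replicate number only, so age, sex, batch and whether replicates came from separate mice are not given in the sources used here. The submitters' processing notes name bcl2fastq, STAR, Subread featureCounts, Salmon and limma with genome build mm10, without the order of the steps.

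The deposited table held 13789 rows for 13744 genes, and 45 repeated rows were left out. Its log2 values per library were made by the authors as the log2 of reads plus 0.5 over the scaled library total plus 1, in CPM (counts per 1e6), before they were deposited, which was checked by undoing the formula with the lowest value of each library as 0 reads. All values then came within 0.01 of whole reads. The authors' table also gave log2 fold changes with confidence limits, p-values and adjusted p-values for each knockout against wild type, per the file headers in the style of limma. These were used only as an alternative. Summed reads per library ran from 46617756 to 62633123, a value of 1 CPM (the normalized unit of reads) stood for 47.9 to 61.8 reads, and mitochondrial transcripts made up 0.569% to 0.778% of reads.

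The log2 CPM values were fitted with limma 3.58.1 in R 4.3.3 (4 group means, all 8 libraries, empirical Bayes with a trend of the prior variance) for 12752 genes with a mean of at least 1 CPM. Each knockout was compared with wild type and with the other knockouts by moderated tests of limma, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The fit had 4 residual and 4.66 prior degrees of freedom. SEs and p-values rest on the assumption that the spread is alike in the 4 groups. In fits that left out 1 library, the lone library of that group was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

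A set of 29 gene lists, written before the data were examined, covered monocyte subsets, monocyte transcription factors, type I interferon-stimulated genes, guanylate-binding and immunity-related GTPases, MHC class I and II presentation, inflammasome, inflammatory, immediate early, reported BCL6 target, Notch, G2/M, S phase, sterol and LXR target genes. It also covered early myeloid, neutrophil, dendritic, macrophage, B, T and NK, erythroid, megakaryocyte, basophil, mitochondrial, ribosomal protein and sex-linked genes. Of 563 list genes 445 were tested. Camera was run for the 27 lists with at least 3 tested members, with a preset correlation of 0.01 and with a correlation estimated per list. With an estimated correlation camera used only the 4 residual degrees of freedom, so its p can rise whatever the correlation. For the plasmacytoid dendritic cell list in Irf2 KO (estimated correlation -0.00628), unadjusted camera p went from 0.00229 to 0.0358. A call lost there does not by itself show that members vary together, and the preset assumes that they hardly do. List medians were set beside those of 10000 random lists matched on expression.

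The genes named in the text were set by a rule made before the data were examined. It takes the targeted genes, the 8 largest rises and 8 largest falls of each comparison with wild type among called protein-coding genes whose libraries do not overlap and whose mean is at least 4 CPM, up to 4 members of each list, and the 10 largest of those called alike in all 3 comparisons. Other genes named here were chosen after their values were seen, to fill in small counts or opposite changes. Some genes that the rule or a small count would name are not reported here. Shared calls were set beside independent lists and 100 simulations of unchanged groups, in which all 8 libraries were drawn around the wild type means. Gene positions, GC content and transcript length came from GENCODE M21 on GRCm38, for 12740 genes.

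The procedure was tested on simulated data with 12752 genes. It recovered 13.4%, 20.9% and 19.4% of changes planted at 1.5-fold for Bcl6 cKO, Irf2 KO and Nr4a1 KO, 50.7%, 58.2% and 62.7% at 2-fold, and 87.9%, 90.9% and 89.4% at 4-fold. Unchanged genes made up 2.88%, 4.24% and 5.00% of calls. With no change planted, camera called 1 of 27 lists for Bcl6 cKO. Each gene was simulated on its own, so this does not check list calls where genes vary together. The estimated correlation of the GTPase list, for one, was 0.98.

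Alternatives set before the data were examined were no trend of the prior variance, no filter on low values, a filter of 4 CPM, quantile normalization, median centring, library weights, only the 2 groups compared, the replicate number as a block, leaving out each library in turn, and the authors' own test results. A correction for GC content and length and limma voom with and without quality weights on recovered reads were chosen after seeing the data. Other pseudocounts and count-based scaling were not run, though the recovered reads would have allowed them.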

Results

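RNA was measured in Ly6C-high classical monocytes of mouse bone marrow, the cells from which Ly6C-low nonclassical (patrolling) monocytes arise. The series asked how the transcription factors Bcl6, Irf2 and Nr4a1 shape these cells before they become nonclassical monocytes. The 8 libraries fell into 4 genotypes with 2 libraries each, namely wild type, a conditional Bcl6 knockout (Bcl6 cKO), an Irf2 knockout (Irf2 KO) and an Nr4a1 knockout (Nr4a1 KO). The labels do not say whether the replicates came from separate mice, so p-values here measure the spread between these samples, which may be technical. Each library held between 46617756 and 62633123 reads assigned to genes, and a value of 1 CPM (the normalized unit of reads) stood for 47.9 to 61.8 reads. Counting error was not set beside the spread between replicates. Changes are given as log2 fold changes ± SE from limma with n = 2 libraries per genotype.

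The targeted genes were examined first. Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795 on GRCm38) lay at 4.96 ± 0.46 log2 CPM (SD, n = 2) in wild type and 2.65 ± 0.47 (SD, n = 2) in Nr4a1 KO, a change of -2.31 ± 0.27 (adjusted p = 0.000622), and both Nr4a1 KO libraries (2.32 and 2.98) lay below both wild type libraries (4.64 and 5.29). Irf2 (ENSMUSG00000031627, chromosome 8, 46739732 to 46847458) was 1.48-fold lower in Irf2 KO, at 6.50 and 6.69 log2 CPM against 7.18 and 7.14 in wild type (-0.56 ± 0.14, adjusted p = 0.0222). Leaving out any single wild type or Irf2 KO library ended that call, with adjusted p up to 0.121. Bcl6 (ENSMUSG00000022508, chromosome 16, 23965052 to 23988852) was 3.52-fold higher, not lower, in the libraries labelled Bcl6 cKO, at 6.53 and 6.40 log2 CPM against 4.66 and 4.64 in wild type (1.81 ± 0.16, adjusted p = 0.00233). Each value counts reads over the whole gene, and which part was deleted is not given in the sources used here. A transcript that has lost some exons is still counted, so the Bcl6 and Irf2 values do not check those labels, and all comparisons below, those of Irf2 KO and Nr4a1 KO with wild type included, rest on the labels as given.

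Each targeted gene was also compared in the other knockouts. Irf2 KO libraries held 2.59 and 2.52 log2 CPM of Nr4a1, a change of -2.41 ± 0.27 (adjusted p = 0.00163) that differed from the one in Nr4a1 KO by -0.09 ± 0.27 (adjusted p = 0.832), and their Bcl6 level fell by 1.07 on the log2 scale (adjusted p = 0.00382). Nr4a1 in the libraries labelled Bcl6 cKO differed from wild type by -0.44 ± 0.27 (adjusted p = 0.393). Bcl6 in Nr4a1 KO (0.05 ± 0.16, adjusted p = 0.872), and Irf2 in the libraries labelled Bcl6 cKO (0.04 ± 0.14, adjusted p = 0.907) and in Nr4a1 KO (0.23 ± 0.14, adjusted p = 0.298), did not pass the test.

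**Figure D1:**
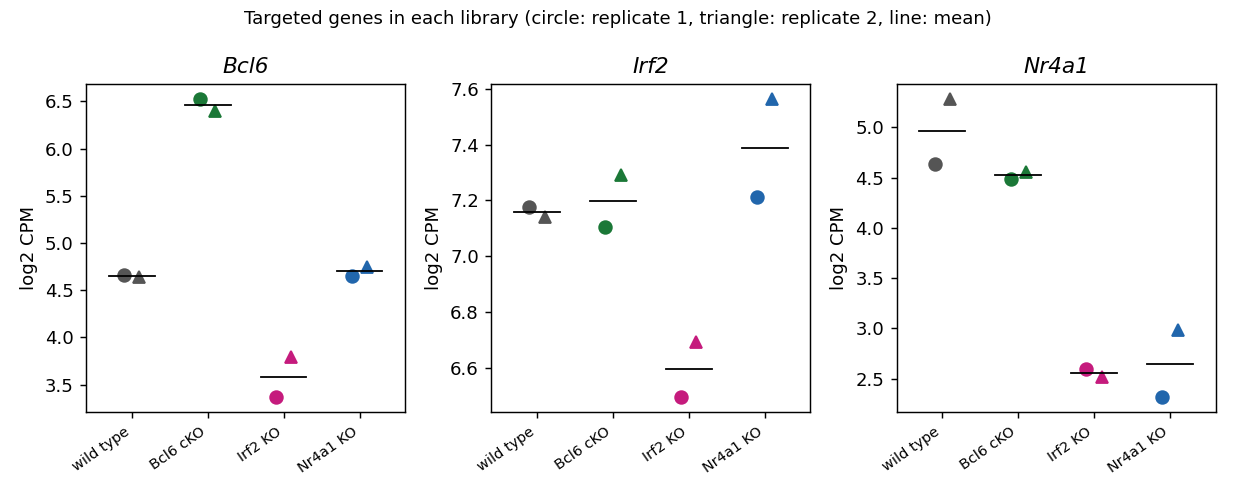
Log2 CPM of Bcl6, Irf2 and Nr4a1 in each of the 8 libraries, by genotype, with circles for replicate 1, triangles for replicate 2 and a line at the mean. Nr4a1 is low in both Irf2 KO (2.59 and 2.52) and Nr4a1 KO (2.32 and 2.98), while Bcl6 is highest in the libraries labelled Bcl6 cKO (6.53 and 6.40).

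The numbers of genes that differed from wild type at an adjusted p under 0.05 (limma, Benjamini-Hochberg, 12752 genes tested) were 639 in the libraries labelled Bcl6 cKO, 2755 in Irf2 KO and 1925 in Nr4a1 KO. Of these, 173, 1181 and 502 were higher and 466, 1574 and 1423 were lower. More than 2-fold changes were seen in 78 higher and 232 lower genes for Bcl6 cKO, 267 and 532 for Irf2 KO, and 78 and 733 for Nr4a1 KO. The balance of directions depended on the scaling between libraries. The share of calls that were higher was 27.1%, 42.9% and 26.1% as deposited, 40.7%, 59.3% and 50.7% after each library was centred on its median, and 39.3%, 53.7% and 47.1% after quantile normalization. Centring raised all log2 fold changes by 0.07 in Bcl6 cKO, 0.10 in Irf2 KO and 0.13 in Nr4a1 KO, so the direction of a smaller change rests on the scaling. Across 12740 genes these fold changes also went down with GC content (Spearman rho -0.32, -0.19 and -0.34). Between the wild type replicates (2 minus 1) rho was 0.21. After a correction for GC content and transcript length 435, 1753 and 1484 genes were called, including 388, 1569 and 1181 of the calls above.

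**Figure D2:**
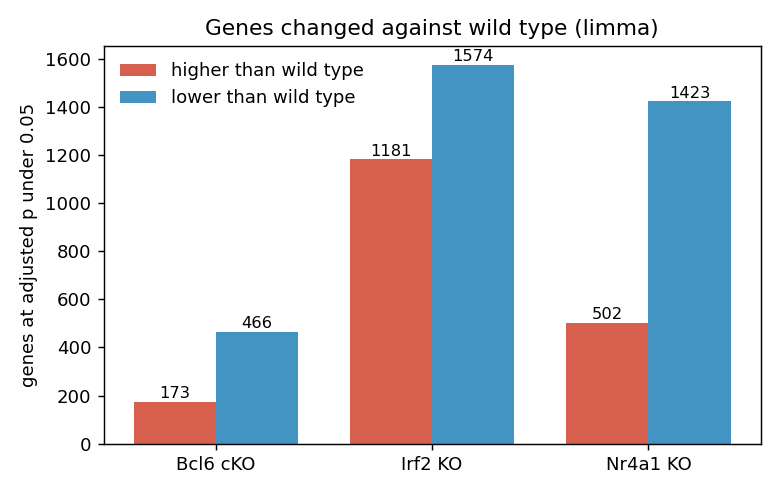
Number of genes higher (red) and lower (blue) than wild type at an adjusted p under 0.05 in each knockout, from limma on 12752 genes. As labelled, falls outnumber rises in all 3 comparisons (466 against 173, 1574 against 1181 and 1423 against 502), an excess that was lost in Irf2 KO and in Nr4a1 KO (1142 falls and 1666 rises, 1145 and 1176) when libraries were centred on their medians.

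In Irf2 KO monocytes some guanylate-binding protein and primary granule genes rose and some nonclassical monocyte genes fell. The largest rises under the naming rule were Gbp2 (42.8-fold, chromosome 3, 142620602 to 142638008), a guanylate-binding protein of the interferon response, and Ccnd2 (25.9-fold, chromosome 6, 127125162 to 127152193), which encodes cyclin D2. The next were Gbp5 (17.9-fold), Shtn1 (14.7-fold), the antiviral genes Ifit1 (13.6-fold), Ifit1bl1 (11.9-fold) and Rsad2 (10.9-fold), and C1qtnf6 (10.0-fold). The Gbp5, Ifit1 and Ifit1bl1 calls each ended when any wild type, Bcl6 cKO or Irf2 KO library was left out (adjusted p up to 0.181, 0.137 and 0.228). The largest falls included Ctso, a lysosomal protease gene (-8.35 ± 1.20), which had 0 and 16 reads in the Irf2 KO libraries, and Cx3cr1 (28.3-fold, chromosome 9, 119901616 to 120069879), the fractalkine receptor gene. Cpq (52.5-fold), Cd209a (50.0-fold, with 266 and 6 reads in the Irf2 KO libraries), Il15ra (27.6-fold), Plaat3 (22.6-fold), Hpgd (16.7-fold), whose enzyme breaks down prostaglandins, and Thbs1 (14.3-fold) also fell. The Cd209a call ended without wild type replicate 1 or 2 (adjusted p up to 0.0978).

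Among 22 tested genes of the nonclassical monocyte list, 10 fell and 2 rose in Irf2 KO, and the same numbers passed when adjusted over the list alone. Cx3cr1 fell by 4.82 ± 0.51, Ace by 4.36 ± 0.71, Adgre4 by 2.71 ± 0.34 and Treml4 by 2.24 ± 0.23 on the log2 scale, all genes of mature Ly6C-low cells, while Lair1 (2.37 ± 0.23) and Cd274 (1.89 ± 0.55) rose. Ace stood at 1.21 and 3.30 log2 CPM in the wild type libraries and below 1 CPM in both Irf2 KO libraries. The list median of -0.62 lay below those of all 10000 random lists of like expression. The list test (camera, preset correlation) gave adjusted p = 0.0124, and adjusted p = 0.410 with an estimated correlation. In the same libraries the markers of neutrophils, B cells and red cells, described below, fell too.

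Of 27 classical monocyte genes, 9 fell and 1 rose in Irf2 KO (9 and 2 adjusted over the list alone). Cd177 and Mmp8 are also in the neutrophil list, and the fall of Cd177 is counted in both lists. The lysozyme genes Lyz2 (-1.04 ± 0.12) and Lyz1 (-0.87 ± 0.10), close paralogs that may share reads, fell with Fn1 (-2.13 ± 0.30) and Thbs1 (-3.84 ± 0.53), while S100a10 rose by 0.58 ± 0.11. Camera gave adjusted p = 0.0456 for this list, and adjusted p = 0.410 with an estimated correlation. That call ended without Irf2 KO replicate 1 (adjusted p = 0.310), wild type replicate 2 (0.0635) or Nr4a1 KO replicate 1 or 2 (0.0533 and 0.0520). Of 34 monocyte transcription factor genes, 10 fell and 1 rose (13 and 1 adjusted over the list alone), with Nr4a1, Bach2 (-2.41 ± 0.38), Relb (-1.43 ± 0.28), Id2 (-1.39 ± 0.23) and Irf4 (-1.66 ± 0.46) lower and Myb (1.05 ± 0.26) higher. Irf2, the targeted gene, is in this list and among the 10 falls and the test of the list. Their camera adjusted p was 0.00735, and adjusted p = 0.410 with an estimated correlation. It became 0.0964 after a correction for GC content and transcript length.

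**Figure D3:**
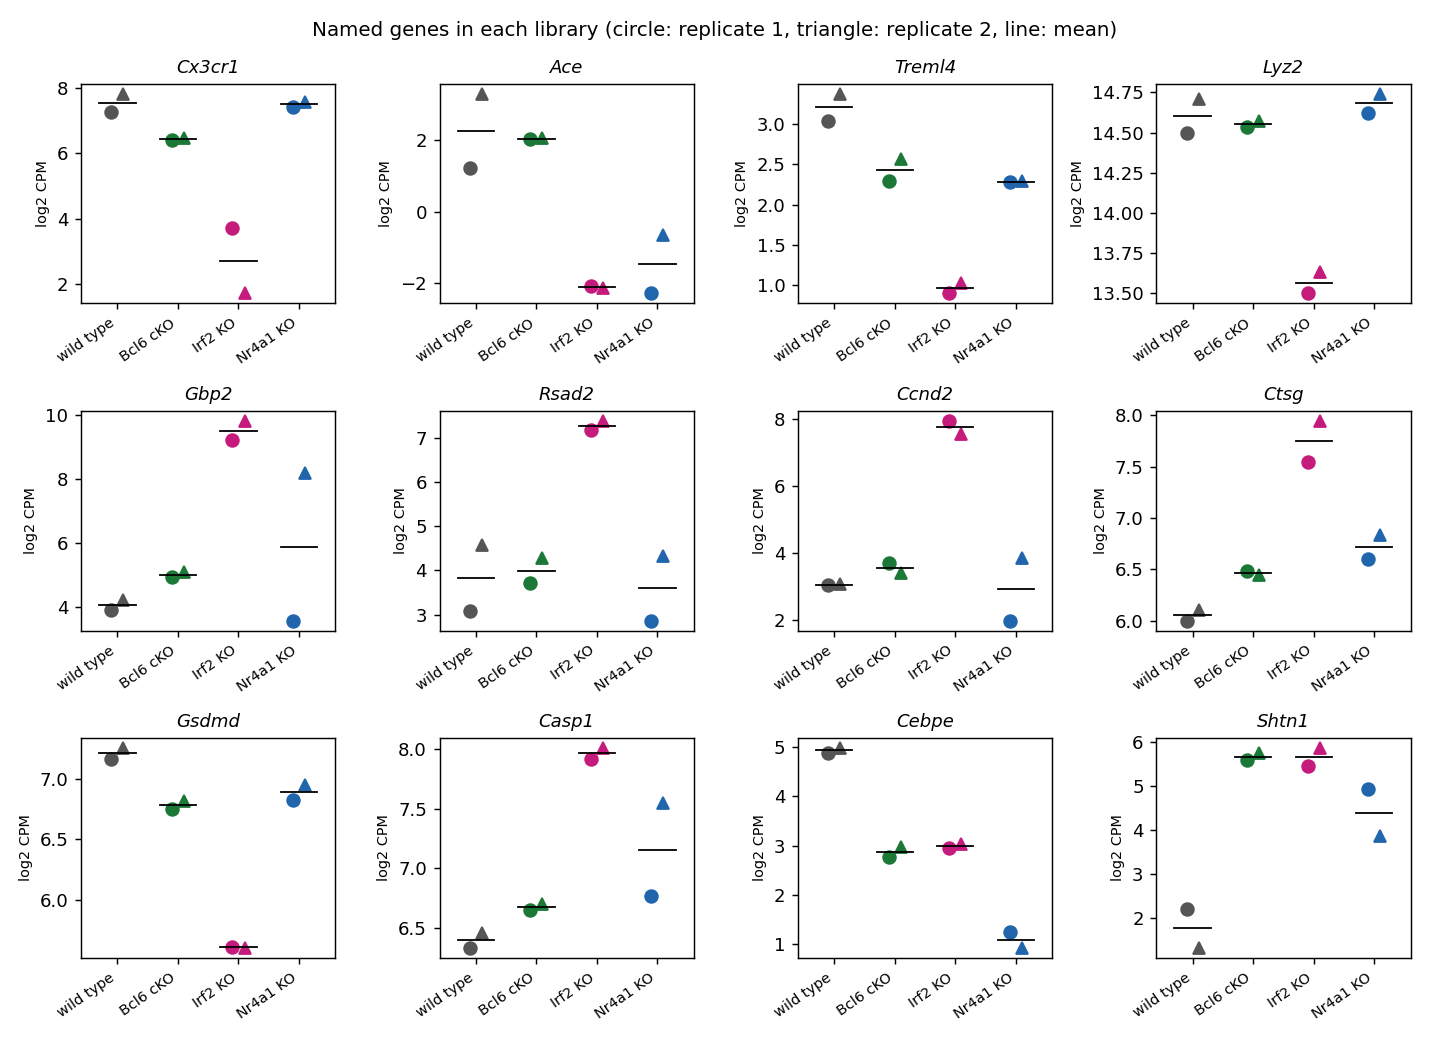
Log2 CPM of 12 genes in each library by genotype, with circles for replicate 1, triangles for replicate 2 and a line at the mean; the vertical axes differ and do not start at 0. Cx3cr1, Treml4, Lyz2 and Gsdmd are lowest and Ccnd2, Rsad2, Ctsg and Casp1 highest in both Irf2 KO libraries, while Cebpe is lower and Shtn1 higher in all 6 knockout libraries than in wild type.

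Interferon-related genes rose in part in Irf2 KO. Of 16 guanylate-binding and immunity-related GTPase genes, 4 rose (5 adjusted over the list alone), namely Gbp2 (5.42 ± 1.12), Gbp5 (4.16 ± 1.24), Gbp3 (3.05 ± 0.70) and Gbp7 (2.48 ± 0.67), with a list median of 2.82. Camera gave adjusted p = 0.00139, and adjusted p = 0.516 with an estimated correlation. Of 41 type I interferon-stimulated genes, 8 rose and 1 fell, also when adjusted over the list alone. Rsad2 (3.45 ± 0.54), Cmpk2 (1.85 ± 0.23), Bst2 (1.73 ± 0.40) and Zbp1 (2.48 ± 0.66) rose, while Ddx58, the RNA sensor RIG-I, fell by 1.97 ± 0.51. The camera adjusted p of 0.0128 became 0.50 without wild type replicate 1 and 0.0798 without Irf2 KO replicate 2, and it was adjusted p = 0.712 with an estimated correlation. The spread within genotypes was wide for both lists, as the plot of interferon-related lists by library shows, and the Gbp2 call ended without wild type replicate 1 or 2 or Irf2 KO replicate 2 (adjusted p up to 0.0684).

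Few antigen presentation genes were called in Irf2 KO. Of 12 MHC class II presentation genes, H2-DMa (-0.98 ± 0.24) and H2-DMb2 (-0.80 ± 0.22) fell (4 fell adjusted over the list alone), and Cd74, the invariant chain, was at -2.61 ± 0.84 (adjusted p = 0.0560). The list median was -1.07 (-0.69 without Irf2 KO replicate 2) and the camera adjusted p 0.00662, and adjusted p = 0.410 with an estimated correlation. Of 20 MHC class I presentation genes, the proteasome activator gene Psme2 rose (1.25 ± 0.34) and H2-D1, which shares sequence with other class I genes, fell (-1.77 ± 0.44). The camera adjusted p of that list was 0.0671. The calls of H2-DMa, H2-DMb2, Psme2 and H2-D1 each ended without wild type replicate 1, among other libraries (adjusted p up to 0.152, for H2-DMb2).

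Genes of cell death and inflammation were examined next in Irf2 KO. Gsdmd, the pore-forming effector of pyroptosis, fell by 1.60 ± 0.10 (adjusted p = 0.000346), whereas Casp1, the protease that cleaves it, rose by 1.57 ± 0.21. Gsdmd was also called lower in the libraries labelled Bcl6 cKO (6.75 and 6.82 log2 CPM, against 7.16 and 7.26 in wild type). That call ended without any 1 of the wild type, Bcl6 cKO and Irf2 KO libraries. Casp1 was also called higher in Nr4a1 KO (6.77 and 7.55, against 6.33 and 6.46), and Ninj1 was called in all 3 comparisons. The Casp1 call in Nr4a1 KO ended without any 1 library other than Nr4a1 KO replicate 1. The Ninj1 call in Bcl6 cKO ended without wild type replicate 1 or Bcl6 cKO replicate 1. In Irf2 KO, 7 of 18 genes of the inflammasome and pyroptosis list fell and 3 rose (9 and 3 adjusted over the list alone). Naip5 (-0.77 ± 0.16), Ninj1 (-1.61 ± 0.23) and Nlrp3 (-0.54 ± 0.16) were among the falls, Pycard (0.49 ± 0.12) and Aim2 (0.57 ± 0.15) among the rises, and the camera adjusted p was 0.160. Of 24 inflammatory and NF-kB genes, 6 fell (8 adjusted over the list alone), with Il1rn at -1.78 ± 0.21, Cxcl2 at -1.89 ± 0.45, Tlr2 at -1.25 ± 0.21 and Nfkb2 at -1.46 ± 0.18. Camera gave adjusted p = 0.00178 for that list, and adjusted p = 0.410 with an estimated correlation.

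Part of the early myeloid and ribosomal protein genes rose in Irf2 KO. Of 15 early myeloid progenitor and primary granule genes, 9 rose and 2 fell (9 and 3 adjusted over the list alone). The granule proteases Ctsg (1.69 ± 0.14), Prtn3 (2.83-fold) and Elane (0.85 ± 0.13), myeloperoxidase (Mpo, 0.94 ± 0.11) and Ms4a3 (2.76 ± 0.41) rose, while Cebpe (-1.93 ± 0.19) and Cd34 (-1.60 ± 0.28) fell. The camera adjusted p was 0.00282, and adjusted p = 0.410 with an estimated correlation. Of 30 ribosomal protein genes 17 rose (22 rose and 1 fell adjusted over the list alone) by small amounts, such as Rpl14 at 0.64 ± 0.08 (camera adjusted p = 1.1e-09, and adjusted p = 0.410 with an estimated correlation). Of 26 S phase genes 3 rose (2 adjusted over the list alone), namely Ccne1 (1.26 ± 0.24), Tyms (0.45 ± 0.10) and Pcna (0.30 ± 0.09), with camera adjusted p = 0.00419, and adjusted p = 0.410 with an estimated correlation. None of these 3 genes stayed called whichever library was left out. Of the 28 G2/M phase genes Cdc20 (-0.88 ± 0.14) and Ccnb2 (-0.68 ± 0.18) fell, and the sign of the list median of -0.04 changed under median centring and without wild type replicate 1 or Irf2 KO replicate 2.

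Markers of other cell types moved with Irf2 KO as well. Of 18 neutrophil genes 8 fell (13 adjusted over the list alone), among them Mmp9 (-2.07 ± 0.30), Csf3r (-1.28 ± 0.09) and the calgranulin genes S100a8 (-1.69 ± 0.41) and S100a9 (-1.66 ± 0.41), with camera adjusted p = 2.5e-05, and adjusted p = 0.410 with an estimated correlation. The size of this fall differed between the Irf2 KO replicates. Beside a list median of -1.32, 15 of the 18 genes were higher in replicate 2 than in replicate 1, with a median difference of 1.49. Of 6 erythroid genes 4 fell and 1 rose (5 and 1 adjusted over the list alone). The globin genes Hba-a1 (-3.39 ± 0.34) and Hbb-bs (-2.64 ± 0.52), each with a near-identical copy, were lower, and the transferrin receptor gene Tfrc (1.46 ± 0.20), which dividing cells also use, was higher. The B cell genes Vpreb3 (-5.84 ± 0.66), Cd79a (-3.91 ± 0.45) and Igkc (-3.28 ± 0.70) fell out of 6 (4 adjusted over the list alone). The plasmacytoid dendritic cell genes Ly6d (-6.68 ± 0.63, with 5 and 1 reads in the Irf2 KO libraries), Bcl11a (-0.89 ± 0.17) and Ccr9 (-1.76 ± 0.52) fell out of 5 (4 adjusted over the list alone). Of 9 conventional dendritic cell genes Cd209a (-5.65 ± 1.38) and Clec10a (-0.47 ± 0.14) fell (5 adjusted over the list alone). Camera gave adjusted p = 0.0282 for the erythroid list (adjusted p = 0.435 with an estimated correlation) and 0.0128, 0.00687 and 0.0461 for the B cell and both dendritic cell lists (each adjusted p = 0.410 with an estimated correlation). The last 3 calls ended under a filter of 4 CPM (0.331, 0.120 and 0.355), and the conventional dendritic cell call also without wild type replicate 1 or 2 (0.0669 and 0.0879).

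The count of 2755 genes in Irf2 KO was 1753 after a correction for GC content and transcript length, and between 1076 and 1522 when a wild type or Irf2 KO library was left out. Among 103 named genes called in Irf2 KO, 54 stayed past the threshold whichever library was left out, including Cx3cr1, Treml4, Nr4a1, Lyz2, Gsdmd, Casp1, Ccnd2, Rsad2, Ctsg, Prtn3 and Ctso.

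The libraries labelled Bcl6 cKO showed fewer changes than the other knockouts. The gap to Nr4a1 KO depended on the fit, at 868 against 1054 genes when only the 2 groups compared were fitted. The largest rises under the naming rule were Shtn1 (14.8-fold, chromosome 19, 58973356 to 59076100), Dcaf1 (7.90-fold), Tmem273 (7.54-fold), Trim30c (6.92-fold), Tmcc3 (6.88-fold), the metalloprotease gene Adam19 (6.40-fold), the purinergic receptor gene P2ry13 (6.19-fold) and Il1rl2 (4.69-fold), a receptor for interleukin 36. The largest falls were Apoe (9.42-fold, chromosome 7, 19696109 to 19699188), the ferritin heavy chain gene Fth1 (9.09-fold), Tpgs1 (7.93-fold), Rps6ka4 (7.02-fold), Hint2 (6.58-fold), Ethe1 (6.34-fold), Mrpl54 (6.28-fold) and Eif4ebp1 (6.26-fold). Of these 16 calls, those for Tmem273, Trim30c, Tmcc3, Adam19, P2ry13, Apoe, Fth1, Tpgs1, Hint2 and Eif4ebp1 ended without Bcl6 cKO replicate 1, and some of them also without other libraries (adjusted p up to 0.157, for Hint2).

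Of the 22 nonclassical monocyte genes, the lipid-sensing nuclear receptor gene Pparg rose by 3.34 ± 0.39, and Itgal (-0.96 ± 0.12) and Pou2f2 (-0.89 ± 0.16) fell (2 and 4 adjusted over the list alone). The Pparg and Itgal calls ended without Bcl6 cKO replicate 1, and the Pou2f2 call without any 1 of the wild type and Bcl6 cKO libraries. The sign of the list median of -0.04 changed under both other scalings and without wild type replicate 2, and camera gave adjusted p = 0.685. Among 34 monocyte transcription factor genes Id1 (-1.06 ± 0.18), Id2 (-1.34 ± 0.23), Irf5 (-0.71 ± 0.10) and Pou2f2 fell, and only Bcl6 itself rose in limma (5 and 4 adjusted over the list alone). Of the 14 Notch pathway genes the ligand gene Jag1 rose by 2.58 ± 0.52. Of 20 reported BCL6 target genes, Bcl6 rose and Id2 fell (1 and 2 adjusted over the list alone), and camera gave adjusted p = 0.748. In the classical monocyte list S100a10 (0.77 ± 0.11) rose and Cd177 (-1.08 ± 0.22), which is also in the neutrophil list, fell, the same numbers as adjusted over the list alone.

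In the libraries labelled Bcl6 cKO, single inflammatory genes changed both ways and part of the neutrophil and cell cycle genes fell, as did 1 B cell and 1 globin gene. Of 24 inflammatory and NF-kB genes, the inhibitor gene Nfkbia (-2.22 ± 0.32), Nfkb2 (-1.10 ± 0.18) and Nod2 (-1.37 ± 0.26) fell and the interleukin 1 antagonist gene Il1rn (1.08 ± 0.21) rose (5 and 1 adjusted over the list alone), with camera adjusted p = 0.685. Of 18 neutrophil genes 4 fell, also when adjusted over the list alone, with Mmp9 at -1.44 ± 0.30 and Fcnb at -0.83 ± 0.18 (camera adjusted p = 0.00056, and adjusted p = 0.891 with an estimated correlation). Of 28 G2/M genes 4 fell (7 adjusted over the list alone), led by Cdc20 (-1.52 ± 0.14) and Cenpa (-0.82 ± 0.10), with camera adjusted p = 0.00201, and adjusted p = 0.967 with an estimated correlation. Mcm5 (-0.44 ± 0.08) and Mcm2 (-0.53 ± 0.12) fell among 26 S phase genes, both also when adjusted over the list alone (camera adjusted p = 0.00469, and adjusted p = 0.967 with an estimated correlation). The G2/M call ended without wild type replicate 1 (0.135) or Bcl6 cKO replicate 2 (0.216), and the S phase call without either of the same libraries (0.237 and 0.200). Of 16 GTPase genes Gbp8 rose (4.39 ± 0.99), a call that ended without Bcl6 cKO replicate 1 among other libraries. The GTPase list and the type I interferon-stimulated list (41 genes) had camera adjusted p of 0.0622 and 0.0678. Of 6 B cell genes Cd79b fell (-0.75 ± 0.15, 3 genes adjusted over the list alone), and of 6 erythroid genes Hba-a1 fell (-1.52 ± 0.34, 1 adjusted over the list alone). Both calls ended without any 1 of the wild type and Bcl6 cKO libraries (adjusted p up to 0.172 and 0.233). The list medians were -0.58 and -0.99, with camera adjusted p = 0.150 for each (adjusted p = 0.891 and 0.967 with an estimated correlation). Without Bcl6 cKO replicate 2 these medians were -1.06 and -0.41.

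The early myeloid list had Nkg7 (1.13 ± 0.21) and Elane (0.53 ± 0.13) higher and Cebpe (-2.06 ± 0.19) lower among 15 genes in the libraries labelled Bcl6 cKO, the same numbers as adjusted over the list alone. Its camera adjusted p of 0.0349 (adjusted p = 0.891 with an estimated correlation) rose to 0.216 without wild type replicate 1 and to 0.0694 and 0.0764 without Bcl6 cKO replicates 1 and 2. The count of 639 genes was lower when any wild type or Bcl6 cKO library was left out, at 33 without Bcl6 cKO replicate 1, 184 without Bcl6 cKO replicate 2, 194 without wild type replicate 1 and 329 without wild type replicate 2, and it was 259 without a trend of the prior variance. Bcl6, Cdc20, Cebpe, Dcaf1, Ethe1, Il1rl2, Mrpl54, Rnaseh2c, Rps6ka4 and Shtn1 stayed past the threshold whichever library was left out, which was true of 10 of the 54 named genes called.

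In Nr4a1 KO part of the cell division genes fell, and falls outnumbered rises among changes of more than 2-fold (733 and 78, or 626 and 162 after median centring). The largest falls under the naming rule were Cox6a1 (24.3-fold, chromosome 5, 115345642 to 115348981) and Cox8a (13.3-fold), subunit genes of cytochrome c oxidase, Alkbh6 (21.5-fold), Ethe1 (17.4-fold), Rps6ka4 (17.0-fold), the granulocyte transcription factor gene Cebpe (14.2-fold, chromosome 14, 54710360 to 54712174), Nop53 (13.6-fold) and Nfkbia (13.6-fold). The largest rises were the MHC class II gene H2-Eb1 (9.12-fold), Adam19 (8.03-fold, chromosome 11, 46055992 to 46147343), Shtn1 (6.12-fold), Myof (4.93-fold), Ms4a3 (3.05-fold), Rnf217 (1.59 ± 0.32 on the log2 scale), C1qtnf6 (2.81-fold) and Tnfsf13 (2.66-fold). The H2-Eb1 and Ms4a3 calls both ended without Nr4a1 KO replicate 2, among other libraries (adjusted p up to 0.156 and 0.134). The Myof call did so too (up to 0.144), and the Rnf217 call ended without wild type replicate 1 (0.0675).

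Of 28 G2/M phase genes, 13 fell in Nr4a1 KO (18 adjusted over the list alone). The mitotic genes Cenpa (-2.40 ± 0.10), Cdca8 (-2.38 ± 0.12), Ube2c (-2.34 ± 0.09) and Cdc20 (-2.31 ± 0.14) fell most, and the list median of -0.45 lay below those of all 10000 random lists. Camera gave adjusted p = 2.0e-10, and adjusted p = 0.903 with an estimated correlation. Of 26 S phase genes 5 fell (8 adjusted over the list alone), including Mcm2 (-0.64 ± 0.12) and Rrm2 (-0.83 ± 0.16), with camera adjusted p = 0.000363, and adjusted p = 0.903 with an estimated correlation.

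Of 22 nonclassical monocyte genes 5 fell in Nr4a1 KO (5 fell and 1 rose adjusted over the list alone), namely Nr4a1 itself, Ace (-3.72 ± 0.71), Pparg (-2.08 ± 0.39), Treml4 (-0.92 ± 0.23) and Pou2f2 (-0.72 ± 0.16), and camera gave adjusted p = 0.504. The Ace call ended without wild type replicate 2 and the Pparg call without wild type replicate 1. The Pou2f2 call ended without wild type replicate 1 or 2 or Nr4a1 KO replicate 2. Of 27 classical monocyte genes 3 rose and 1 fell, also when adjusted over the list alone. The chemokine receptor gene Ccr2 (0.50 ± 0.13), Mgst1 (0.63 ± 0.12) and S100a4 (0.70 ± 0.14) rose and vimentin (Vim, -1.09 ± 0.13) fell. None of these 3 rises stayed called whichever library was left out. Among 34 transcription factor genes Id1 (-3.72 ± 0.18), Irf5 (-0.92 ± 0.10), Nr4a1 and Pou2f2 fell and Zeb2 (0.38 ± 0.10) was among the genes that rose (5 fell and 2 rose adjusted over the list alone). The sign of that list's median of -0.00342 changed under both other scalings and without wild type replicate 2 or Nr4a1 KO replicate 1.

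Inflammatory genes changed in both directions in Nr4a1 KO. Il1b rose by 1.87 ± 0.35, a call that ended without wild type replicate 2 (adjusted p = 0.0574), and Nfkbia fell by 3.76 ± 0.32 and Nfkb2 by 1.06 ± 0.18 among 24 genes, the same numbers as adjusted over the list alone. In the early myeloid list Ctsg (0.66 ± 0.14), Ms4a3 (1.61 ± 0.41), Igfbp4 (0.59 ± 0.15) and Nkg7 (0.81 ± 0.21) rose and Cebpe (-3.83 ± 0.19) fell among 15 genes (4 and 2 adjusted over the list alone), with camera adjusted p = 0.446. Of these only the fall of Cebpe stayed called whichever library was left out. Of 6 B cell genes Cd79a (-2.39 ± 0.45) and Blnk (-2.19 ± 0.63) fell (4 adjusted over the list alone), and of 6 erythroid genes Hba-a1 fell (-1.18 ± 0.34, 1 adjusted over the list alone). The list medians were -1.24 and -1.04, with camera adjusted p of 0.289 and 0.101 (both adjusted p = 0.903 with an estimated correlation). The Hba-a1 call ended without any 1 of the wild type, Bcl6 cKO and Nr4a1 KO libraries, the Blnk call without 5 of the libraries, and the Cd79a call without wild type replicate 2 (adjusted p up to 0.183, 0.180 and 0.0533). In all 6 knockout libraries the medians of the B cell and erythroid lists lay below the wild type mean, at -1.36 and -0.98 for B cell genes and -1.40 and -0.63 for erythroid genes in Nr4a1 KO.

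Interferon-related lists split the Nr4a1 KO replicates. The median of the 16 GTPase genes lay 0.91 below the wild type mean in replicate 1 (-0.91) and 2.65 above it in replicate 2, and the medians of 41 type I interferon-stimulated genes were -1.37 and 0.39. Over both replicates the camera adjusted p was 0.125 and 0.174, Gbp8 rose (3.52 ± 0.99, a call that ended without Nr4a1 KO replicate 2 among other libraries), and the correlation of log2 CPM between the Nr4a1 KO replicates (r = 0.971, across genes) was the lowest of the 4 genotypes. That correlation was no higher than their highest with other genotypes (also 0.971), whereas replicates of each other genotype correlated better with each other. The count of 1925 genes became 1535 without Nr4a1 KO replicate 2 and 1775 without replicate 1. It was 1065 without wild type replicate 2, and 1054 when only the wild type and Nr4a1 KO libraries were fitted. Of 74 named genes called, 33 stayed past the threshold whichever library was left out, among them Cenpa, Ube2c, Cdca8, Cdc20, Cebpe, Id1, Nfkbia, Cox6a1, Adam19 and Shtn1.

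**Figure D4:**
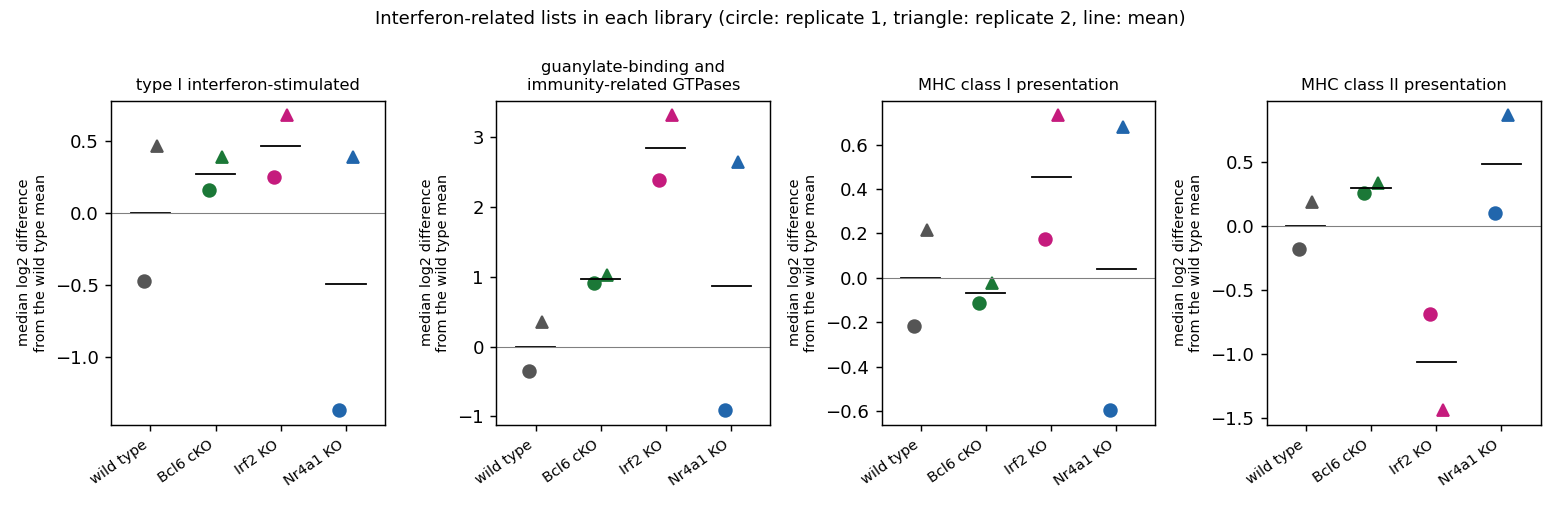
Median log2 difference from the wild type mean of the genes in 4 interferon-related lists, 1 point per library, with circles for replicate 1, triangles for replicate 2 and a line at the mean of the replicates. By the mean of its replicates Irf2 KO lies highest for the GTPase genes (2.39 and 3.32), and the Nr4a1 KO replicates stand on opposite sides of 0 (-0.91 and 2.65).

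**Figure D5:**
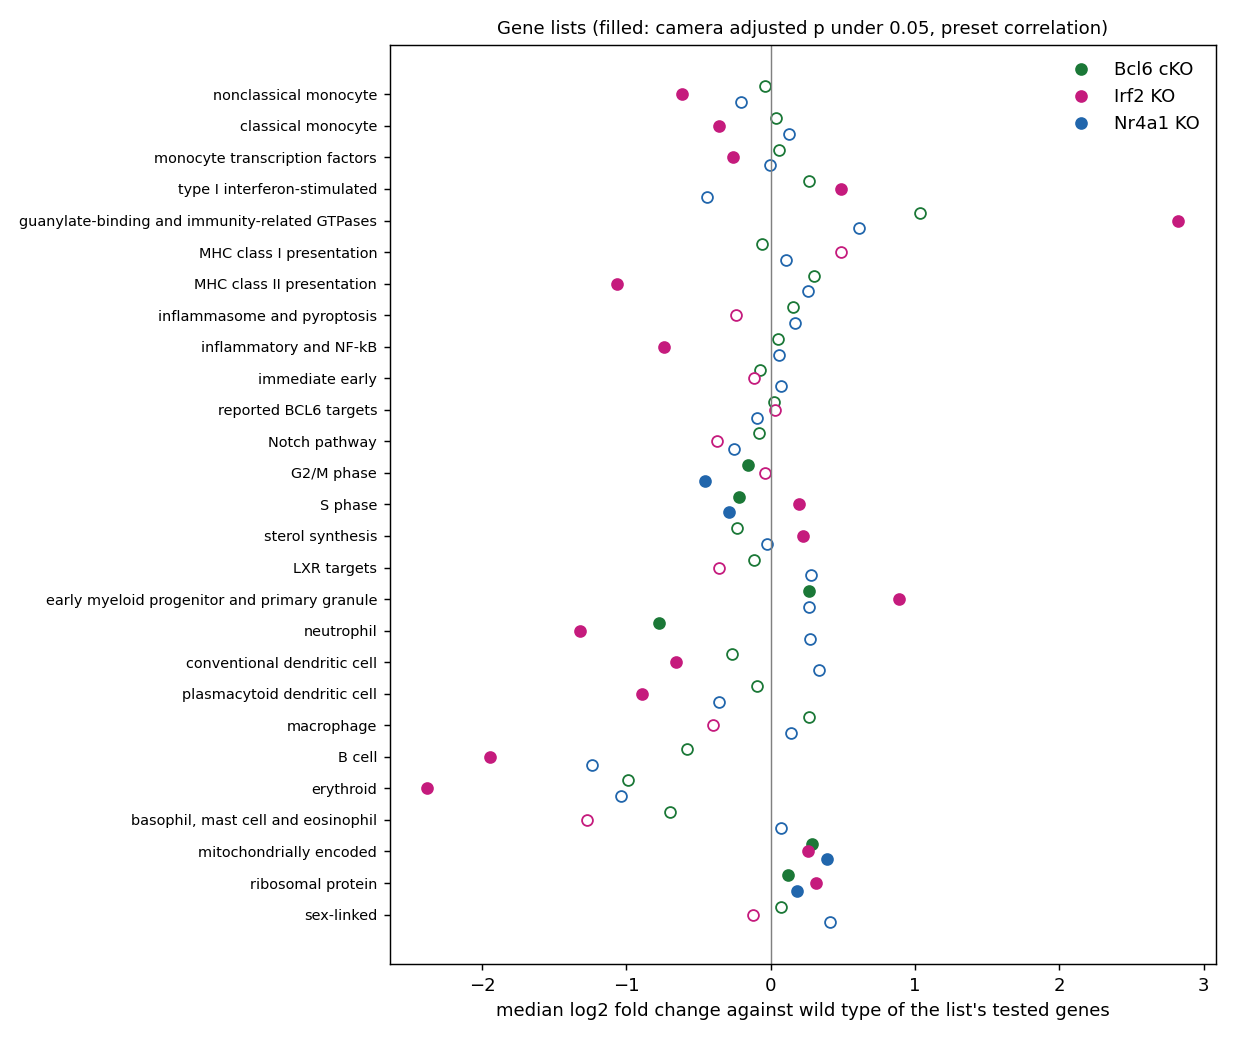
Median log2 fold change against wild type of the tested genes in each of 27 gene lists, 1 point per knockout, filled where camera with a preset correlation gave an adjusted p under 0.05. Most filled points belong to Irf2 KO (17, against 6 for Bcl6 cKO and 4 for Nr4a1 KO), and no list passed with an estimated correlation, where the lowest adjusted p was 0.410. That version used only the 4 residual degrees of freedom, so a lost call does not by itself show that list members vary together.

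Some mitochondrially encoded genes were called higher in each knockout. Of 13 genes, 2 rose in the libraries labelled Bcl6 cKO, 4 in Irf2 KO and 7 in Nr4a1 KO (7, 5 and 8 adjusted over the list alone), with mt-Atp8 higher by 2.82-fold and mt-Co2 by 0.59 ± 0.11 on the log2 scale in Nr4a1 KO. Camera gave adjusted p of 2.4e-05, 0.00317 and 0.000139, and adjusted p of 0.891, 0.410 and 0.903 with an estimated correlation. The direction of the list median changed in all 3 comparisons after the correction for GC content and length (-0.03, -0.14 and -0.08). The ribosomal protein list (30 genes) was also called higher in Bcl6 cKO and Nr4a1 KO, at camera adjusted p = 0.00347 and 0.000375 (adjusted p = 0.967 and 0.903 with an estimated correlation), with small medians of 0.12 and 0.18. In Bcl6 cKO no single gene of the list passed, also when adjusted over the list alone, and the list call ended without wild type replicate 1 (0.216) or Bcl6 cKO replicate 2 (0.271), where the medians were 0.07 and 0.05. In Nr4a1 KO 3 genes rose and 1 fell (7 and 1 adjusted over the list alone). Rpl14 (0.37 ± 0.08) and Rpl11 (0.32 ± 0.09) were among the rises, and Rpl13 (-2.03 ± 0.46) fell. The Rpl11 call ended whichever library was left out (adjusted p up to 0.185), the Rpl14 call without wild type replicate 1 or 2, and the Rpl13 call without Nr4a1 KO replicate 1.

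The knockouts were then compared with each other. Irf2 KO and Nr4a1 KO differed in 2850 genes (1583 higher and 1267 lower in Irf2 KO), the libraries labelled Bcl6 cKO and Irf2 KO in 1218 (724 and 494 higher and lower in Bcl6 cKO), and Bcl6 cKO and Nr4a1 KO in 733 (634 and 99). For Irf2 KO and Nr4a1 KO the higher and lower genes numbered 1442 and 1382 after median centring and 1396 and 1443 after quantile normalization. The balance of the other pairs kept its direction under both scalings. Cx3cr1 was lower in Irf2 KO than in Nr4a1 KO by -4.77 ± 0.51 (adjusted p = 0.000413). Ace, low in both, differed by -0.63 ± 0.71 (adjusted p = 0.564). It lay at -2.07 and -2.13 log2 CPM in Irf2 KO and at -2.28 and -0.65 in Nr4a1 KO. All of these are below 1 CPM, so the missing call does not show equal levels. Pparg, at opposite ends in Bcl6 cKO and Nr4a1 KO, differed by 5.41 ± 0.39 (adjusted p = 0.000152). Lyz2 was lower in Irf2 KO than in Nr4a1 KO (-1.12 ± 0.12, adjusted p = 0.000408), and Ccnd2 was higher (4.83 ± 0.48, adjusted p = 0.000305). The mitotic genes Ube2c and Cenpa were lower in Nr4a1 KO than in both others, with Bcl6 cKO minus Nr4a1 KO at 2.05 ± 0.09 (adjusted p = 3.7e-05) and 1.58 ± 0.10 (adjusted p = 0.00012). The counts for Bcl6 cKO against Irf2 KO and Nr4a1 KO fell to 138 and 367 without Bcl6 cKO replicate 1 and to 155 and 250 without replicate 2. Without Irf2 KO replicate 1 or 2, the Bcl6 cKO and Irf2 KO count was 590 or 356, and that of Irf2 KO and Nr4a1 KO 1734 or 1460.

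Many genes changed the same way in more than 1 knockout. The shared calls numbered 390 for Bcl6 cKO and Irf2 KO (78 higher and 312 lower in both), 454 for Bcl6 cKO and Nr4a1 KO (69 and 385), and 734 for Irf2 KO and Nr4a1 KO (267 and 467). The balance of directions rested on the scaling. After median centring the higher and lower shared calls were 137 and 218, 143 and 316, and 600 and 297 for the same pairs, and after quantile normalization 127 and 232, 137 and 319, and 508 and 325, so that for Irf2 KO and Nr4a1 KO the balance reversed. Independent lists of the same sizes would share 16.0 and 57.5, 6.81 and 52.0, and 46.5 and 175.6 genes higher and lower. All 3 comparisons use the same wild type libraries. In 100 simulations all 8 libraries were drawn around the wild type means, each gene on its own, and shared calls averaged 0.07, 0.03 and 0.07. With no gene changed almost none is called, so these averages are no baseline for the shared calls. They do not measure a shift of the real wild type libraries. The fold changes of the pairs correlated across genes at r = 0.49, 0.63 and 0.35, beside a simulated 0.50 for each pair, and their covariances of 0.154, 0.195 and 0.145 exceeded the simulated 0.0381, 0.0379 and 0.0379 by 0.116, 0.157 and 0.107. The 2 wild type libraries were not split, since each part would hold 1, so part of the excess may come from the shared controls. The shared counts fell to 27 and 28 for the Bcl6 cKO pairs without Bcl6 cKO replicate 1 and to 119 and 159 without replicate 2. They were 116, 153 and 398 without wild type replicate 1 and 198, 263 and 279 without wild type replicate 2. Without Irf2 KO replicate 1 or 2 they were 161 or 188 for Bcl6 cKO and Irf2 KO and 283 or 321 for Irf2 KO and Nr4a1 KO.

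In all 3 comparisons 49 genes were higher and 256 were lower than in wild type, against 105 and 174 after median centring, 97 and 185 after quantile normalization and 28 and 137 after the correction for GC content and length. The genes with the largest mean change among them were Fth1 (-3.18, -2.45 and -3.41 in Bcl6 cKO, Irf2 KO and Nr4a1 KO), Shtn1 (3.89, 3.88 and 2.61), Tpgs1 (-2.99, -2.41 and -3.38) and Ethe1 (-2.66, -1.69 and -4.12), followed by Cebpe, Rps6ka4, Eif4ebp1, Hint2, Lsm4 and Rnaseh2c, all lower in each knockout. The wild type replicates themselves differed for some of these, with SDs of 1.45 for Lsm4, 1.31 for Tpgs1 and 0.83 log2 CPM for Fth1, against 0.07 for Cebpe and 0.15 for Rnaseh2c.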

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

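All technical explanations weighed in this part were tested only after the result was seen.

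Some genes were called in opposite directions against wild type in 2 knockouts. They numbered 13 for Bcl6 cKO and Irf2 KO, 8 for Bcl6 cKO and Nr4a1 KO and 56 for Irf2 KO and Nr4a1 KO. The difference between the knockouts passed the test for all of them. That outcome was all but fixed, since the difference exceeds each change at the same SE, so it adds no support. The numbers were not set beside those of independent lists. Between Bcl6 cKO and Irf2 KO, 12 genes were higher in the first and lower in the second, among them the lectin gene Clec4n (difference 5.95 ± 0.49), Cd33, Pilra and Cd14 (2.15 ± 0.23), and 1 gene, Selenom, went the other way (-1.49 ± 0.12). Between Bcl6 cKO and Nr4a1 KO, 5 genes were higher in the first and lower in the second (Pparg, Cd164, Sema4b, Rnf144b and Gsto1), and 3 went the other way (Jaml, Gm9733 and Clec12a). Between Irf2 KO and Nr4a1 KO, 37 genes were higher in the first and lower in the second, among them the mitochondrial ribosome gene Mrpl12 (3.41 ± 0.14), and 19 went the other way, among them Il1b (-3.12 ± 0.35), Ccl6 (-2.18 ± 0.15) and Cd14. The numbers depended on single libraries: with 1 library left out, genes that went opposite ways numbered 1 to 31 for Bcl6 cKO and Irf2 KO, 1 to 20 for Bcl6 cKO and Nr4a1 KO, and 7 to 96 for Irf2 KO and Nr4a1 KO.

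The 256 genes lower in all 3 comparisons had a median GC content of 54.6%, against 48.9% for other tested genes. A GC and length trend between libraries as the whole cause is argued against, because the correction kept at least 81.24% of their median change. Medians of Bcl6 cKO, Irf2 KO and Nr4a1 KO went from -1.08, -0.89 and -1.44 to -0.92, -0.72 and -1.22, with 169, 176 and 206 of the genes still past the threshold and 130 past it in all 3, so the trend may account for part of the calls. A shift of wild type replicate 1 or of both wild type libraries stays open: the 93.12% or more of the median change kept against replicate 2 alone decides nothing, since both wild type libraries of every chosen gene lay above the knockouts by selection, and knockouts that differ from each other, as Irf2 KO and Nr4a1 KO did in 129 of these genes (50.4%, against 21.8% of other genes) and Bcl6 cKO and Irf2 KO in 34 (13.3%, against 9.48%), exclude no such shift. An untested biological effect shared by the knockouts, and the exchange of labels weighed next, stay open too.

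Bcl6 was higher in the libraries labelled Bcl6 cKO. If these labels were exchanged with wild type, Nr4a1 KO might be expected to resemble the libraries labelled Bcl6 cKO in Bcl6, but it lay -1.766 log2 units from them and near wild type. Against that, Nr4a1 KO and Irf2 KO differed from the libraries labelled Bcl6 cKO in 733 and 1218 genes and from wild type in 1925 and 2755, so an exchange of labels and a true rise cannot be told apart here. Under an exchange, the 466 falls and 173 rises of Bcl6 cKO would trade places. The counts against true wild type would be 1218 in Irf2 KO (494 higher and 724 lower) and 733 in Nr4a1 KO (99 and 634), and genes lower in all 3 comparisons would include genes raised by loss of Bcl6. A transcript without the deleted exons that escapes control by its own protein may also be the reason, which was not tested and would need reads per exon.

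The interferon-induced GTPase genes were higher in Nr4a1 KO replicate 2 than in replicate 1 by a median of 3.56 log2 units (16 of 16 genes), against 0.71, 0.13 and 0.68 in wild type, Bcl6 cKO and Irf2 KO (16, 11 and 16 genes). The type I interferon-stimulated genes were also higher in replicate 2 of every genotype, by 0.94, 0.20, 0.48 and 1.77 in wild type, Bcl6 cKO, Irf2 KO and Nr4a1 KO (41, 34, 36 and 41 of 41 genes). Among lists of other cell types with at least 5 tested genes, the largest median difference was 1.499 (5 basophil, mast cell and eosinophil genes). That is below the lower quartile of the GTPase genes (2.695), which argues against cells of these types as the cause. Other cell types stay open, since the T and NK cell list (2 tested genes) and the megakaryocyte list (1) were too small to weigh. Of 12 MHC class II genes 10 were also higher in replicate 2, with a median of 0.65 and an upper quartile of 2.86. A GC and length trend is argued against as well, with 3.553 left after the correction. No biological explanation was tested, since both libraries carry the same label, and a difference that goes with the replicate number, such as a batch, stays open.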

How the results depend on the processing

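The correction for GC content and length and the voom fits were chosen after seeing the data, and the other alternatives before. Of the gene counts, 132 stayed within 1.5 times the value in the report, 44 were lower and 1 was higher. Without a trend of the prior variance, 259 genes differed in Bcl6 cKO and 537 between Bcl6 cKO and Irf2 KO, and shared calls were 137 (Bcl6 cKO and Irf2 KO), 187 (Bcl6 cKO and Nr4a1 KO) and 451 (Irf2 KO and Nr4a1 KO). With only the 2 groups compared, counts were 1054 in Nr4a1 KO, 1947 for Bcl6 cKO and Irf2 KO, 484 for Bcl6 cKO and Nr4a1 KO, 1770 for Irf2 KO and Nr4a1 KO, and 406 shared by Irf2 KO and Nr4a1 KO. After the GC and length correction, 1753 genes differed in Irf2 KO, shared calls were 218, 300 and 338 in the order above, and mt-Nd6 reversed to -0.020 in Bcl6 cKO and -0.15 in Nr4a1 KO. The mitochondrially encoded list reversed to -0.033, -0.14 and -0.082 in Bcl6 cKO, Irf2 KO and Nr4a1 KO. The causes were not tested. Leaving out 1 library gave 33 to 917 genes in Bcl6 cKO, 1076 to 3190 in Irf2 KO, 1065 to 1775 in Nr4a1 KO, 138 to 1647 for Bcl6 cKO and Irf2 KO, 250 to 859 for Bcl6 cKO and Nr4a1 KO and 1460 to 2705 for Irf2 KO and Nr4a1 KO. Shared calls ran from 27 to 564, 28 to 543 and 279 to 759. In Nr4a1 KO the type I interferon-stimulated list ran from -1.37 to 0.39, the GTPase list from -0.91 to 2.65 and MHC class I from -0.60 to 0.68, the low value without replicate 2 and the high value without replicate 1 of Nr4a1 KO. With the replicate number as a block, 626, 2716 and 1861 genes differed from wild type in Bcl6 cKO, Irf2 KO and Nr4a1 KO. The authors' own results gave 893, 2929 and 1429, of which 633, 2697 and 1424 were also called here. Among values of named genes 6481 kept direction and side of the threshold, 728 lost the call, 249 gained it and 2 reversed. For lists the numbers were 1493, 60, 55 and 6. Other pseudocounts and count-based scaling were not run, though reads had been recovered. A value of 1 CPM stood for at least 47.9 reads, and the effect of depth was not tested.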

Other observations

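The lists in this part were written before the data were examined, and the tests near the targeted genes and the values of single genes outside the naming rule were chosen only after results were seen.

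In Irf2 KO, 5 of 14 Notch pathway genes fell (7 fell and 1 rose adjusted over the list alone), led by Maml2 (-2.14 ± 0.46), Mfng (-0.76 ± 0.16) and Tspan14 (-0.58 ± 0.09), with a camera adjusted p of 0.0629, and adjusted p = 0.410 with an estimated correlation. Notch1 (-0.70 ± 0.15) and Tspan14 (-0.50 ± 0.09) fell in Nr4a1 KO (3 fell and 1 rose adjusted over the list alone). Of 20 reported BCL6 target genes, Ccnd2 (4.70 ± 0.48) and Cxcr4 (0.45 ± 0.12) rose in Irf2 KO, and 5 genes fell, including Bcl2l1 (-0.77 ± 0.17) and Gpr183 (-0.56 ± 0.12), also when adjusted over the list alone. Of 24 immediate early genes, 6 fell in Irf2 KO, including Btg2 (-1.36 ± 0.14) and Junb (-1.11 ± 0.34), and Hspa1b rose (4.61 ± 1.41), with 7 and 1 adjusted over the list alone and a camera adjusted p of 0.0907. Dnajb1 fell in Bcl6 cKO (-1.28 ± 0.20) and Nr4a1 KO (-1.86 ± 0.20).

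Lipid genes changed in small numbers. Of 9 LXR target genes, Apoe fell in Bcl6 cKO (-3.24 ± 0.50) and Irf2 KO (-3.26 ± 0.50), Srebf1 fell in Bcl6 cKO (-1.20 ± 0.18) and Nr4a1 KO (-1.55 ± 0.18), Fasn (0.86 ± 0.15) and Scd2 (1.06 ± 0.26) rose in Irf2 KO and Abcg1 (0.84 ± 0.24) rose in Nr4a1 KO. Of 19 sterol synthesis genes, Insig1 (0.80 ± 0.23) and Stard4 (0.55 ± 0.13) rose and Mvd (-0.45 ± 0.14) fell in Irf2 KO (1 rose adjusted over the list alone). The camera adjusted p was 0.0461, and adjusted p = 0.536 with an estimated correlation, and the call ended without Irf2 KO replicate 2 (0.363), wild type replicate 2 (0.0838) or Nr4a1 KO replicate 1 or 2 (0.0537 and 0.0533). Srebf2 fell in Nr4a1 KO (-0.95 ± 0.17).

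In the remaining lists few genes were called. Of 9 macrophage genes Adgre1 (-1.16 ± 0.11) and Slc40a1 (-1.86 ± 0.42) fell in Irf2 KO, and Axl fell (-1.69 ± 0.34) in Nr4a1 KO. Of 5 basophil, mast cell and eosinophil genes Prss34 (-3.02 ± 0.78) and Ear1 (-1.27 ± 0.31) fell in Irf2 KO (camera adjusted p = 0.0737). Of 2 tested T and NK cell genes Nkg7 rose in all 3 knockouts, and the 1 tested megakaryocyte gene, Itgb3, fell in Irf2 KO (-1.34 ± 0.28). None of these calls of Nkg7 and Itgb3 held whichever library was left out. Medians of 4 sex-linked genes were 0.07, -0.12 and 0.41 in Bcl6 cKO, Irf2 KO and Nr4a1 KO, and camera gave adjusted p of 0.685, 0.714 and 0.101. In Nr4a1 KO the MHC class II list (12 genes) had H2-Eb1 (3.19 ± 0.82) and H2-DMb1 (0.78 ± 0.17) higher, with a camera adjusted p of 0.101.

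Near the targeted genes, within 10 Mb on each side, the share of called genes did not differ past the threshold from that elsewhere (Fisher's exact test), at 6 of 145 genes for Bcl6 cKO (p = 0.847), 13 of 41 for Irf2 KO (p = 0.128, adjusted p = 0.383) and 16 of 108 for Nr4a1 KO (p = 1). Near Irf2 on chromosome 8, Cyp4v3 (-3.37 ± 0.32), Stox2 (-2.85 ± 0.41) and Hpgd (-4.07 ± 0.41) fell in Irf2 KO, and near Bcl6 on chromosome 16 Lpp rose in Bcl6 cKO (1.73 ± 0.32). Igf2bp3 stood at 4.64 and 3.69 log2 CPM in the wild type libraries and at 0.60 or less in the 6 knockout libraries.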
